A study of Mus musculus with 18 samples.

How the data were processed

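RNA of colonic differentiated cells and colonic stem cells from SPF and GF mice was extracted with a kit that yields DNA and RNA from the same cells, and 200 ng of total RNA entered each library, per the labels' protocols. The submitters' processing notes name Bowtie2, RSEM and DESeq, with no version, role or order, and the genome build mm10. The values used are the authors' deposited table of SPF against GF, whose columns are a log fold change (read as log2, since the header does not give the base), a p-value and an adjusted p-value per gene symbol. The column names are those that edgeR writes while the submitters' notes list DESeq, so the tool behind the authors' values is not settled. Which samples, which cell type, which covariates and which filter entered is not given in the sources used here. The sign was kept as the header reads, SPF over GF, although the direction planned before the data were examined was GF minus SPF.

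Recomputing the Benjamini-Hochberg adjustment from the deposited p-values over all 14239 genes gave the authors' adjusted p within 1% for 14239 genes (largest difference 0.680%), so the listed genes are the full set over which the p-values were adjusted. The planned tests on values per sample could not be run on this unit, and the plan's fallback was used: the authors' log fold change and adjusted p, with a gene called at an adjusted p under 0.05. Depth per sample is unknown, so no counting interval or floor is given.

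The 32 gene lists were fixed before the data were examined, from general knowledge of colon epithelium, microbial responses, chromatin regulators and other cells that the samples could hold. For each list the members called each way were counted, over all genes and again with p adjusted over the list alone, and the median was placed among 10000 random lists of the same size. The plan matched those lists on mean level, which the table does not give, so they were unmatched, and matched on transcript length as an alternative. A test of each list against all other genes was added after the data were seen: cameraPR (limma 3.58.1, R 4.3.3), two-sided, on the signed z of the deposited p-value with a preset correlation of 0.01 and Benjamini-Hochberg over the 32 lists. An estimated correlation needs values per sample and was not run. Symbol families were formed from shared symbol stems with at least 12 listed genes and tested the same way.

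The rule for named genes was fixed before the data were examined. It takes the 8 largest rises and 8 largest falls among genes at an adjusted p under 0.05 without a predicted or clone name, up to 3 members of each list with the smallest adjusted p, and Lgr5. Its limit on mean level could not be applied. A gene that the rule takes is not reported here, which leaves 97, and the other genes in the text were chosen after their values were seen.

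Transcript length and GC content are those of the longest transcript per symbol in GENCODE vM21, whose assembly GRCm38 is the one also called mm10, and 13898 of the symbols (97.6%) matched. For the length-centred values the median log fold change of each of 20 bins of transcript length was taken off, with the spread of a gene taken from its deposited p-value, and p-values were adjusted again. Each step was first tested on simulated data: with a length trend and 200 planted changes over 14239 genes, the length-centred step recovered 78% of 2-fold and 91% of 4-fold changes in SPF against GF and called 12 genes without one. The planted changes were unrelated to length and far fewer than the 4813 genes called in the data. The simulation therefore does not show how the step acts where many genes of like length truly change. Other alternatives were adjusted p limits of 0.01 and 0.1, a 2-fold limit, protein-coding genes only, the Benjamini-Yekutieli adjustment, a preset correlation of 0.05, ranks in place of z, and lists without shared members. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.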

Results

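RNA was sequenced from colonic stem cells and differentiated cells of 15-week-old C57BL/6J mice that carry an EGFP and inducible Cre reporter at Lgr5, the marker gene of intestinal stem cells. The mice were kept either under specific-pathogen-free (SPF) conditions, with a gut microbiota, or germ-free (GF), without one. The 18 samples comprised differentiated cells from 6 SPF samples (2 male, 4 female) and 8 GF samples (5 male, 3 female), and stem cells from 2 SPF samples (1 male, 1 female) and 2 GF samples (2 female, 1 of them marked as a second batch). The values analysed are a comparison made by the authors, SPF against GF, which gives a log fold change, a p-value and an adjusted p-value for each of 14239 genes. It holds no value per sample, so the depth of each sample is unknown and no spread between samples or n can be set beside a value. The adjusted p of the authors' deposited table is the measure of error, except where an error implied by the deposited p-value is named. The table does not say which of the 18 samples or which cell type entered, or whether sex was a term. Each value below therefore describes colonic cells of SPF against GF mice as the authors compared them. Positive values are higher in SPF, as the header reads, and the log is read as base 2, which the header does not state.

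The comparison asks how the presence of a microbiota changes gene expression in the colonic epithelium. The largest difference was in Lrg1, a secreted glycoprotein of the acute phase, which was 972-fold higher in SPF in the authors' deposited table (log fold change 9.92, adjusted p = 1.16e-13). Also among the largest in the authors' deposited table were Lcn2, an iron-sequestering antimicrobial protein (8.18, adjusted p = 7.98e-11), Reg3b (7.97) and Reg3g (6.28), antibacterial lectins, lactoferrin Ltf (6.57), the inducible nitric oxide synthase Nos2 (6.55) and the constant region of IgA, Igha (5.50). The largest differences the other way in the authors' deposited table were in Galnt17, a glycosyltransferase family member (-5.69, adjusted p = 1.34e-05), the cytochrome P450 gene Cyp2c69 (-5.42), the mitochondrial malic enzyme Me3 (-4.39), the membrane peptidase Mme (-4.26), the potassium channel Kcnh1 (-4.10), Nrn1 (-3.97), Cyp11a1, the enzyme that starts steroid hormone synthesis (-3.59), and Plscr2 (-3.54). Altogether 4813 genes, 33.8% of those listed, passed an adjusted p of 0.05 in the authors' deposited table, 2549 higher and 2264 lower in SPF. Of these, 1103 differed by at least 2-fold, 624 higher and 479 lower, by the authors' deposited table. Genes with close copies, among them Reg3b and Reg3g, Cyp2c69, the H2 genes and the Gbp and Oas families, can share reads, and their values are uncertain to that extent.

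In mm10 coordinates, Lrg1 lies on chromosome 17 from 56119678 to 56122001 and Lcn2 on chromosome 2 from 32384633 to 32388252. Reg3b and Reg3g lie near each other on chromosome 6, from 78370657 to 78373466 and from 78466269 to 78468872. Ltf occupies 111019271 to 111042767 on chromosome 9 and Nos2 78920787 to 78960254 on chromosome 11. Among the genes lower in SPF, Galnt17 lies on chromosome 5 from 130872082 to 131308497, Cyp2c69 on chromosome 19 from 39842814 to 39886799, and Me3 on chromosome 7 from 89632392 to 89854359. These are whole-gene spans, and each of these genes is annotated as protein-coding.

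**Figure D1:**
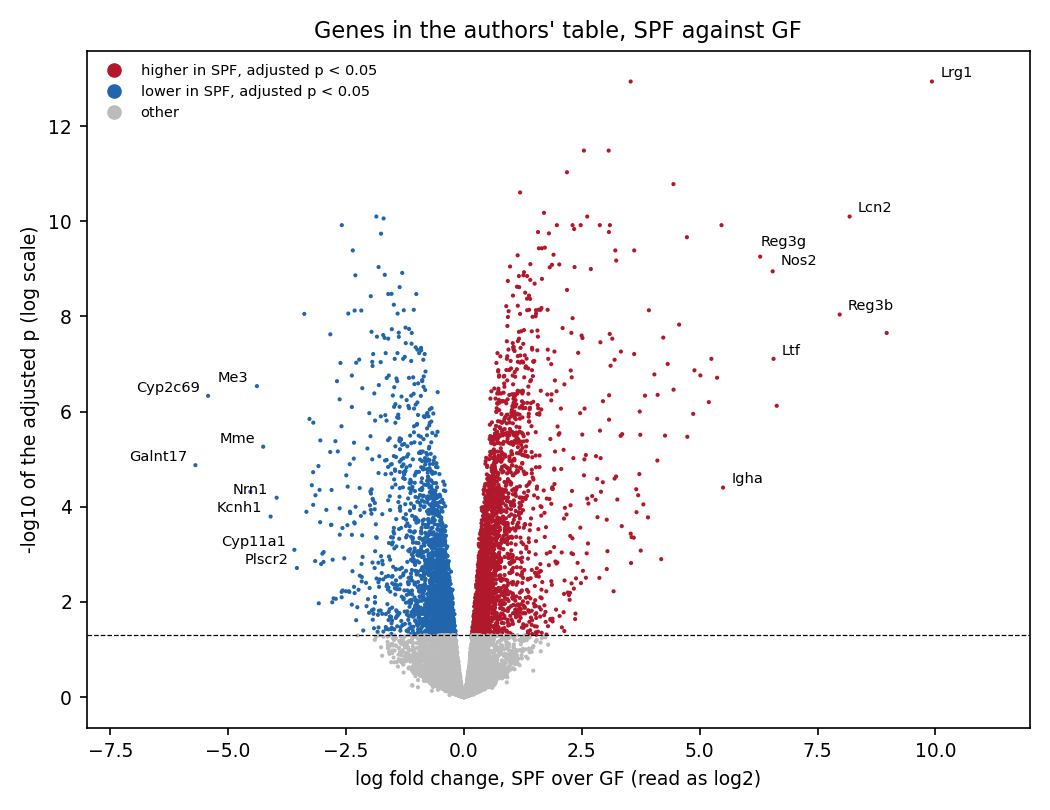
Each point is 1 of the 14239 genes of the authors' deposited table, with the log fold change (SPF over GF, read as log2) on the x axis and -log10 of the adjusted p on the y axis. The dashed line marks an adjusted p of 0.05, red points are the 2549 genes higher in SPF and blue points the 2264 lower, and names mark genes among the largest differences each way, from Lrg1 at 9.92 to Galnt17 at -5.69.

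Antigen presentation and interferon-response genes were higher in SPF as groups. Of the 8 listed genes for MHC class II presentation, 7 were higher and none lower in the authors' deposited table, with a median of 4.87. They included the master regulator Ciita (4.73), the invariant chain Cd74 (5.25), the peptide-loading gene H2-DMa (3.92) and H2-Eb1 (5.37), while Ctss did not pass the threshold (-0.11) in the authors' deposited table. Of 15 genes for MHC class I presentation, 14 were higher and 0 lower, with a median of 1.17, in the authors' deposited table. Examples from the authors' deposited table are the light chain B2m (1.65), the peptide transporter Tap1 (2.35), H2-K1 (1.27) and the transactivator Nlrc5 (4.86). Of 39 interferon-response genes, 32 were higher and 0 lower (median 1.44) in the authors' deposited table, among them Parp9 (1.14), the immunity-related GTPases Irgm1 (1.17) and Irgm2 (2.19), and Ifi47 (4.04). Adjusted over the list alone, 7, 14 and 35 members of these 3 lists were higher and 0 lower. All 3 lists differed from the other genes (cameraPR with a preset correlation of 0.01, Benjamini-Hochberg over 32 lists, adjusted p = 4.50e-08, 1.48e-13 and 4.41e-21), and each median lay above that of all 10000 random lists of its size.

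Antimicrobial and mucosal defence genes were higher in SPF as a group, with exceptions among goblet cell products. Of 23 listed members, 12 were higher and 3 lower (median 1.25) in the authors' deposited table, and the counts adjusted over the list alone were 12 and 3 (cameraPR, adjusted p = 2.14e-06). Besides Lcn2, Reg3b, Reg3g and Nos2, the NADPH oxidase Nox1 (2.55), the oxidase maturation factor Duoxa2 (3.07), the phospholipase Pla2g2a (4.44) and the resistin-like Retnlb (2.55) were higher in the authors' deposited table. The 3 members lower in SPF in the authors' deposited table were the lectins Zg16 (-1.97) and Itln1 (-1.52) and Wfdc2 (-0.76). Among 27 microbe-sensing genes 8 were higher and 2 lower (median 0.15) in the authors' deposited table, and 8 and 3 adjusted over the list alone. The lipopolysaccharide co-receptor Cd14 (1.57), the peptidoglycan-binding Pglyrp1 (1.02) and the inflammatory caspase Casp4 (0.81) were higher and the flagellin receptor Tlr5 (-0.94) lower in the authors' deposited table. This list passed the test (cameraPR, adjusted p = 0.0213) but not with a preset correlation of 0.05 (adjusted p = 0.122) or without a member shared with another list (adjusted p = 0.0638). The NF-kB, cytokine and chemokine list did not pass (cameraPR, adjusted p = 0.0864). It held 8 genes higher and 3 lower of 22 in the authors' deposited table, and as many adjusted over the list alone, with Nfkbiz (1.80) and Tgfb1 (1.18) higher and the alarmin Il33 (-1.52) lower.

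Cell cycle and cholesterol synthesis genes were higher in SPF. All 20 cell cycle genes passed in that direction in the authors' deposited table, with a median of 1.19, among them the replication helicase subunit Mcm5 (1.52), the topoisomerase Top2a (1.26) and thymidylate synthase Tyms (1.06). Of 19 cholesterol synthesis genes, 18 were higher and 0 lower (median 0.76) in the authors' deposited table, among them Mvd (1.01), Nsdhl (0.76) and the squalene epoxidase Sqle (1.03). Adjusted over the list alone, the counts were 20 and 18, and both lists differed from the other genes (cameraPR, adjusted p = 6.68e-18 and 2.26e-08). The stem cell list did not (cameraPR, adjusted p = 0.678): 5 of its 19 listed members were higher and 3 lower (median 0.05) in the authors' deposited table, and 6 and 3 adjusted over the list alone. Prom1 was higher (0.91), and Tgfbi (-1.33) and the Wnt receptor ligase Znrf3 (-0.62) were lower in the authors' deposited table. Lgr5 itself, on chromosome 10 from 115450311 to 115587780, had a log fold change of -0.38 that did not pass the threshold in the authors' deposited table (adjusted p = 0.374).

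Goblet cell and deep crypt secretory cell genes were lower in SPF. Of 19 goblet cell genes, 13 were lower and 2 higher (median -0.76) in the authors' deposited table, with Klk1 (-1.18), the stress sensor Ern2 (-0.79), the mucin Muc2 (-0.64) and Clca1 (-1.88) lower and Muc13 (0.64) and Retnlb higher. Of 14 deep crypt secretory cell genes, 8 were lower and 0 higher (median -0.49) in the authors' deposited table, among them the receptor Kit (-1.36), the Notch ligand Dll1 (-1.28) and Mxd4 (-0.86). Adjusted over the list alone, 13 goblet genes were lower and 2 higher, and 9 deep crypt secretory genes were lower and 0 higher (cameraPR, adjusted p = 0.000698 and 6.62e-05). Of 17 tuft cell genes, the leukotriene synthase Ltc4s (-1.10) and the channel Trpm5 (-0.61) were the 2 that passed in the authors' deposited table, both lower, and 1 was lower adjusted over the list alone. Of 20 enteroendocrine genes, the progenitor factor Neurog3 was the 1 that passed (0.62, adjusted p = 0.0487) in the authors' deposited table, and 0 passed adjusted over the list alone. Neurog3 lost its call in length-centred values (adjusted p = 0.0727). The absorptive list held 2 genes higher and 4 lower of 20 in the authors' deposited table, the same counts as adjusted over the list alone, among them the retinol dehydrogenase Dhrs9 (3.20), the guanylin gene Guca2a (-1.13) and the phosphate transporter Slc20a1 (-0.81). None of these 3 lists passed as a group (cameraPR, adjusted p = 0.137, 0.745 and 0.698), and the absorptive list's median (-0.14) and mean (0.03) differed in sign in the authors' deposited table.

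Glycan and transport genes had more members lower than higher in SPF. Of 27 glycosylation genes, 11 were lower and 5 higher (median -0.21) in the authors' deposited table, with the sialyltransferases St6gal1 (-1.33) and St3gal6 (-0.93) and B3gnt7 (-1.18) lower and Fut1 (0.71) higher. Of 25 ion and water transport genes, 9 were lower and 2 higher (median -0.27) in the authors' deposited table, with the kinase Sgk1 (-1.36) and the carbonic anhydrase Car2 (-0.68) lower and the water channel Aqp4 (1.05) higher. The counts adjusted over the list alone were the same. Both lists passed (cameraPR, adjusted p = 0.0266 and 0.0459) and neither did with a preset correlation of 0.05 (adjusted p = 0.135 and 0.180). Of 6 bile acid genes, 2 were higher and 2 lower in the authors' deposited table, also when adjusted over the list alone, with the ileal bile acid transporter Slc10a2 (-2.84) and Slc51a (-1.17) lower and the bile acid binding Fabp6 (1.41) higher. The bile acid list did not pass (cameraPR, adjusted p = 0.790), and its median (0.03) and mean (-0.38) differed in sign in the authors' deposited table.

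Fatty acid oxidation genes were lower in SPF. Of 23 listed members, 11 were lower and 1 higher (median -0.21) in the authors' deposited table and adjusted over the list alone, with the coactivator Ppargc1a (-1.21) and the dehydrogenase Acadm (-0.62) lower and the ketone body enzyme Bdh1 (0.45) higher (cameraPR, adjusted p = 0.00328). Of 27 nuclear oxidative phosphorylation genes, Cycs (0.62), Cyc1 (0.33) and Atp5b (0.23) were the 3 that passed in the authors' deposited table, all higher, and 2 did adjusted over the list alone. That list did not pass as a group (cameraPR, adjusted p = 0.0824), though it did with ranks (adjusted p = 0.0252), and Atp5b lost its call in length-centred values (adjusted p = 0.129). Xenobiotic response genes went both ways, with 6 higher and 9 lower of 28 in the authors' deposited table, 7 and 10 adjusted over the list alone, and did not pass as a group (cameraPR, adjusted p = 0.612). The quinone reductase Nqo1 (1.41) and the glutathione transferase Gsta3 (2.31) were higher and the efflux pump Abcb1a (-1.61) lower in the authors' deposited table.

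Regulators of DNA and histone methylation, of interest because the study concerns the epigenetics of intestinal stem cells, went both ways. Of 24 genes for DNA methylation and its removal, 6 were higher and 6 lower in the authors' deposited table, also when adjusted over the list alone. The maintenance methyltransferase Dnmt1 (0.90) and its partners Uhrf1 (1.57) and Hells (1.31) were higher, and the demethylating Tet1 (-1.64) and Tet3 (-0.72) and the methyltransferase Dnmt3a (-0.52) lower, in the authors' deposited table. Of 34 histone acetylation and methylation genes, 9 were higher and 13 lower in the authors' deposited table, 9 and 14 adjusted over the list alone. The deacetylases Hdac1 (0.54) and Hdac3 (0.49) and the methyltransferase Ezh2 (0.63) were higher, and Ezh1 (-0.60), Kmt2a (-0.96) and Kmt2d (-0.89) lower, in the authors' deposited table. Neither list passed as a group (cameraPR, adjusted p = 0.698 and 0.287). All 20 cell cycle genes were also higher (median 1.19) in the authors' deposited table. Whether the rise of Dnmt1, Uhrf1, Hells and Ezh2 goes beyond that difference in proliferation genes was not tested. Transcript length went with the histone list, whose median was -0.17 in the authors' deposited table and -0.02 once the median of genes of like length was taken off.

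Clock genes were lower in SPF. Of 17 listed members, 10 were lower and 2 higher (median -0.83) in the authors' deposited table, and 10 and 3 adjusted over the list alone (cameraPR, adjusted p = 0.000698). Lower in the authors' deposited table were Per1 (-1.05), Per3 (-1.45), the nuclear receptors Rora (-2.73) and Nr1d1 (-1.98), and Dbp (-1.94), and the 2 higher genes were Cry1 (1.07) and Arntl (0.47). The unfolded protein and stress list did not pass (cameraPR, adjusted p = 0.734), with 9 genes higher and 12 lower of 27 in the authors' deposited table, and 11 and 13 adjusted over the list alone. Sdf2l1 (1.38), Calr (0.82) and Asns (1.10) were higher, and Herpud1 (-0.74), Ddit3 (-0.83), Atf3 (-1.11), Fos (-0.75) and Egr1 (-0.70) lower, in the authors' deposited table. The tight junction and adhesion list had few members past the threshold, with 4 genes higher and 1 lower of 25 in the authors' deposited table and adjusted over the list alone (cameraPR, adjusted p = 0.690). The higher ones included Cldn2 (0.47), Cldn7 (0.31) and the desmosomal Pkp2 (0.26) in the authors' deposited table, and the list's median (-0.01) and mean (0.04) differed in sign. In length-centred values Cldn7 (adjusted p = 0.0844) and Pkp2 (adjusted p = 0.0675) lost their calls.

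T cell and NK cell markers moved with the defence and antigen presentation genes, and the other immune, stromal and red blood cell lists did not pass. Most members of these lists were absent: 10 of 22 T cell and NK cell, 6 of 17 B cell and plasma cell and 5 of 21 macrophage and dendritic cell markers were listed. So were 6 of 21 stromal and 7 of 21 small intestine and Paneth cell markers. The filter is not given, so the counts and tests cover only the members that passed it. Of 10 listed T cell and NK cell markers, 7 were higher and 0 lower (median 1.70) in the authors' deposited table, 8 and 0 adjusted over the list alone (cameraPR, adjusted p = 0.0165). The granzyme Gzma (4.18), the chemokine Ccl5 (2.33), the kinase Lck (0.96) and Cd3e (2.03) were higher, and the pan-leukocyte Ptprc (-0.30) did not pass, in the authors' deposited table. Igha (5.50) and the light chain Igkc (3.03) were the 2 of 6 listed B cell and plasma cell markers that passed in the authors' deposited table, and Cd14 the 1 of 5 macrophage and dendritic cell markers, with the same counts adjusted over the list alone (cameraPR, adjusted p = 0.145 and 0.269). Of 6 stromal markers, Vim (0.84) was higher and Pdgfrb (-0.48) lower in the authors' deposited table, 1 and 2 adjusted over the list alone (cameraPR, adjusted p = 0.565). Neither of the 2 red blood cell markers passed in either count (cameraPR, adjusted p = 0.802). Of 7 small intestine and Paneth cell markers, 5 were lower and 1 higher (median -1.50) in the authors' deposited table and adjusted over the list alone, with the brush border enzymes Sis (-2.21) and Anpep (-1.81) and Apob (-1.50) lower. That list passed (cameraPR, adjusted p = 0.0311) but not with a preset correlation of 0.05 (adjusted p = 0.0690), with ranks (adjusted p = 0.0551) or without members shared with another list (adjusted p = 0.0717). None of 8 sex-linked genes passed in either count (cameraPR, adjusted p = 0.698).

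**Figure D2:**
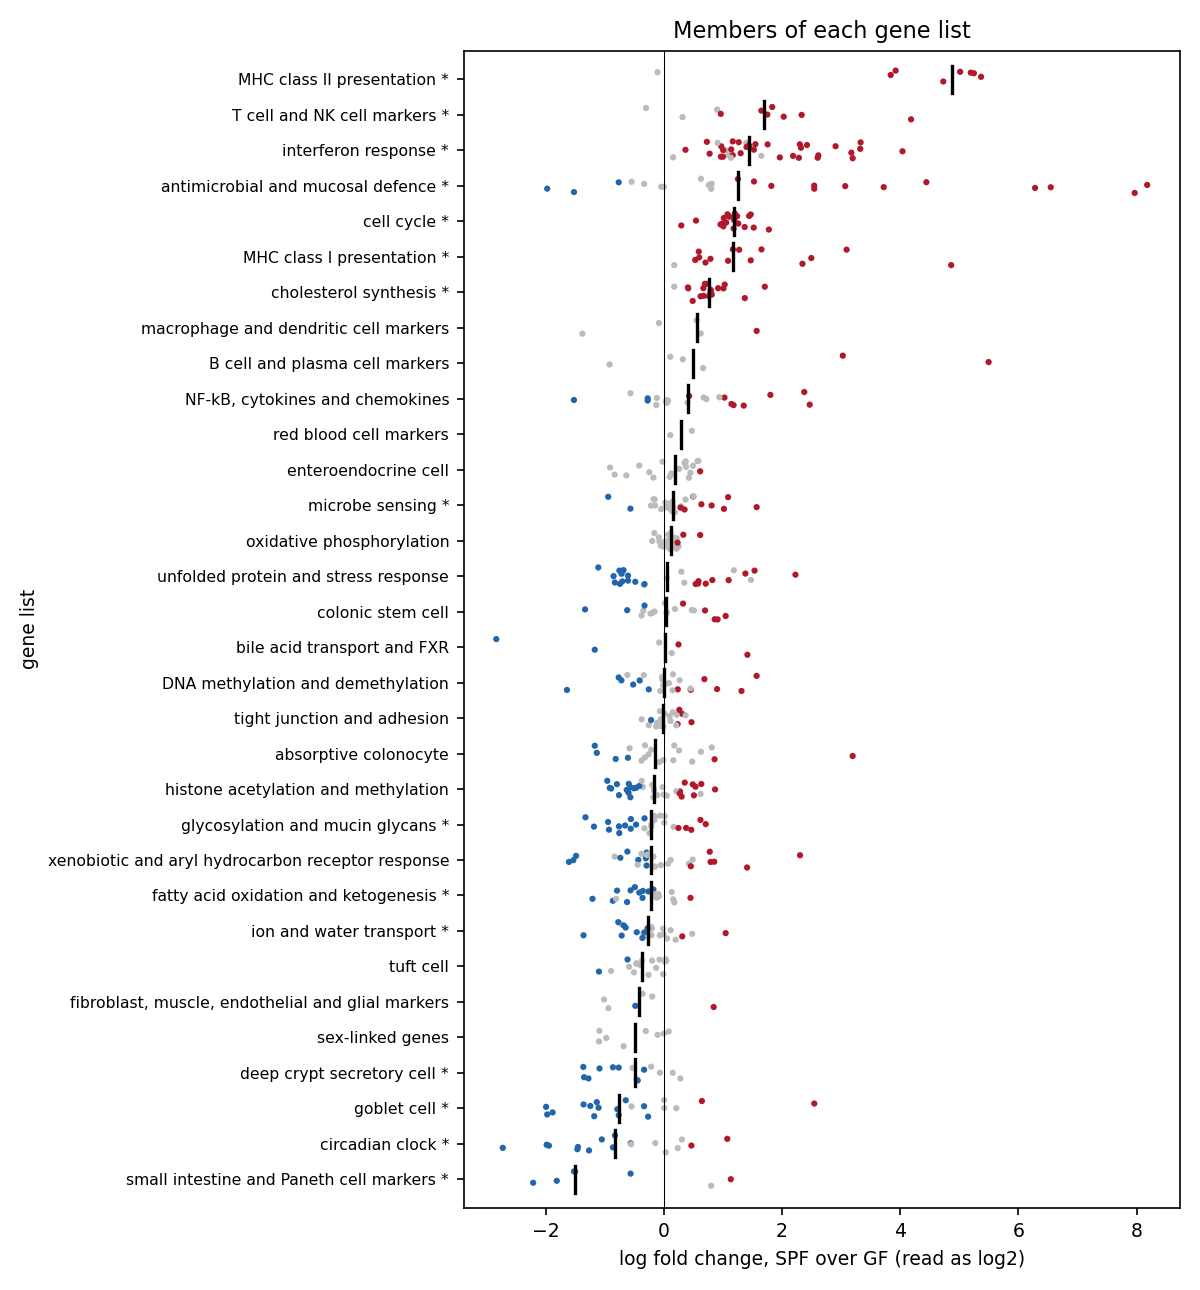
Each point is a listed member of a gene list, at its log fold change in the authors' deposited table (SPF over GF, read as log2), red where higher and blue where lower in SPF at an adjusted p under 0.05 and grey otherwise; black bars are list medians and vertical scatter carries no meaning. Asterisks mark the 15 of 32 lists that passed cameraPR, from MHC class II presentation (median 4.87) to small intestine and Paneth cell markers (median -1.50).

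Transcript length moved with the direction of the difference. Among the decile of longest transcripts, 33.7% of genes were lower and 8.21% higher in SPF in the authors' deposited table, against 7.34% lower and 13.9% higher among the shortest. Across 13898 genes, which are not independent replicates, Spearman's rho between the signed z of the p-value and transcript length was -0.20. The comparisons of stem with differentiated cells, of SPF with GF within each cell type, and of the difference between cell types need values per sample and were not analysed here.

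**Figure D3:**
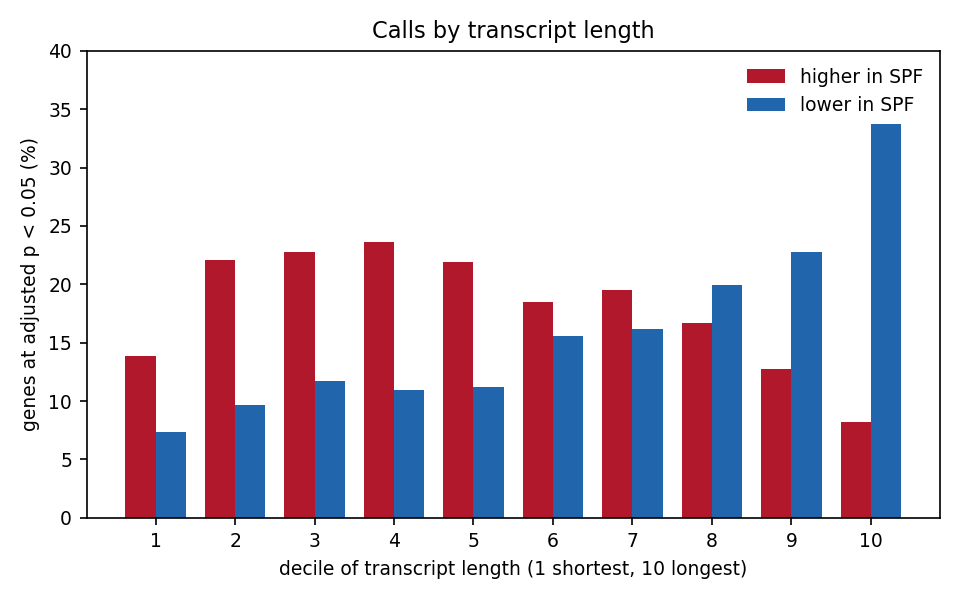
Bars give the percentage of genes at an adjusted p under 0.05 in the authors' deposited table that were higher (red) or lower (blue) in SPF, by decile of the length of each gene's longest annotated transcript. The share lower in SPF is 7.34% in the shortest decile and 33.7% in the longest.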

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

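The alternatives on protein-coding genes, the Benjamini-Yekutieli adjustment, transcript length, preset correlation, ranks and shared members were chosen after the data were seen. Of the planned limits, an adjusted p of 0.01 left 3135 genes of 4813, with 1322 lower in SPF, and adding a 2-fold limit left 1103, 624 higher and 479 lower. The Benjamini-Yekutieli adjustment left 2624, 1563 higher and 1061 lower. The smaller counts follow from a stricter limit on the same p-values or, for the 2-fold limit, on the fold change. The other settings gave 4340 to 5841 genes, within 1.5 times the main count, and 11 to 15 lists against 15.

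Of 97 named genes, 93 kept their side of the threshold and their direction in length-centred values (not Neurog3, Atp5b, Cldn7 and Pkp2), 92 at an adjusted p of 0.01, 87 with the Benjamini-Yekutieli adjustment and 69 with the 2-fold limit. Among the lists, the sign turned for the mean of absorptive (0.034), bile acid (-0.38) and tight junction genes (0.037), for absorptive genes without shared members (0.16), and in length-centred values for tight junction (0.0018) and stress genes (-0.0067); none of these lists passed, and the cause was not tested. With a preset correlation of 0.05, 4 lists no longer passed: microbe sensing, ion and water transport, glycosylation, and small intestine and Paneth cell markers. The last also failed with ranks and, like microbe sensing, without shared members, and oxidative phosphorylation passed with ranks alone.

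No paired analysis was possible because the table holds no values per sample. For the same reason leaving out replicates, other splits of the samples, the sample marked as a second batch, a sex term, other normalizations, tests, pseudocounts and level filters, and an estimated correlation were not run. Depth is unknown, so its limit on low genes cannot be given.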

Other observations

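Except for the tests of Y-linked genes in all, differentiated or stem cells, of immune and secretory marker lists as causes of the defence pattern, overall length and GC content, Nnt and the clock, the groups and tests below were chosen after the data were seen. The symbol families, 110 in all, gave 16 at an adjusted p under 0.05 (cameraPR), of which 4 lost it in length-centred values. Proteasome subunits led: 35 of 38 Psm genes were higher in SPF and 0 lower, with a median of 0.55 in the authors' deposited table (adjusted p = 7.06e-18). Mitochondrial ribosomal proteins (36 of 77 higher, 0 lower, adjusted p = 6.83e-08) and nucleoporins (14 of 20 higher, 0 lower, adjusted p = 5.22e-06) were also higher in the authors' deposited table. RNAs encoded by the mitochondrial genome went the other way: 17 of 27 were lower and 0 higher (median -0.85, adjusted p = 5.22e-06), with the ribosomal RNAs mt-Rnr1 (-2.30) and mt-Rnr2 (-2.41) and the oxidase subunit mt-Co3 (-2.03) among them in the authors' deposited table. These RNAs share a genome and are not independent. The preset correlation of 0.01 treats them as nearly so, and their adjusted p is likely far too small. Zinc finger genes named Zfp (58 of 337 lower, 11 higher) and Cyp genes (15 of 34 lower, 3 higher) were lower as families in the authors' deposited table (cameraPR, adjusted p = 0.00874 and 0.00137). Among all 14239 genes, 2264 were lower and 2549 higher. The share of Zfp genes called lower was thus near that of all genes, and few were called higher (family median -0.18).

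Some complement and cytokine receptor genes, untested as groups, were also called. Of 9 listed complement genes, C3 (3.61), C4b (3.56), C2 (2.14) and C1ra (1.36) were higher and the membrane inhibitor Cd59a (-2.26) lower, while Cfb (-0.02) did not pass, in the authors' deposited table. The oncostatin M receptor Osmr (4.74) was higher, and the receptors Lifr (-3.06), Il6ra (-2.47) and Il11ra1 (-0.87), which also signal through the shared subunit Il6st, were lower in the authors' deposited table. The downstream Stat3 (0.50), Socs3 (1.90) and Bcl3 (0.64) were higher in the authors' deposited table. Of 7 listed genes of the interleukin-1 family and its receptors, 3 were lower, Il1r1 (-0.83), Il1rap (-0.63) and Il33 (-1.52), and 1 higher, Il18bp (1.53), in the authors' deposited table. The predicted gene Gm42517, on chromosome 5 from 108366073 to 108367922, had the second largest value of all, 8.97, in the authors' deposited table.

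The rise of defence and antigen presentation genes came with T cell markers and with Igha and Igkc, though not Ighm (-0.92, adjusted p = 0.357), in the authors' deposited table. A larger share of goblet and deep crypt secretory cells in SPF is argued against, since the higher of those 2 list medians was -0.49. RNA of macrophages, dendritic cells or B cells as the whole cause of the class II rise is also argued against: the 11 listed markers of these cells had a median of 0.55 (SD over markers 1.92), far below the class II median of 4.87. For the other defence genes, RNA from T cells, B cells or macrophages stays open, since the medians of the 3 marker lists, of which the lowest was the B cell median of 0.49, met neither bound: the T cell (1.70) and macrophage (0.55) medians lay above 0.5, but 2 of 6 B cell and 1 of 5 macrophage markers were called, and without the shared Cd14 the macrophage median was 0.24. A response of epithelial cells to the microbiota is the biological hypothesis the design names, and it stays open as well.

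Longer transcripts were lower in SPF, and a technical part may be involved. A shift shared by genes of like length is argued against as the whole cause of the 4813 calls. In length-centred values 81.0% of called genes of known length stayed called with the same sign. That step takes off only the median of each length bin. An effect of integrity or coverage that varies among genes of like length was not tested. A bias that rises or falls steadily with GC content is argued against by a rho of 0.034 across genes. A bias against both low and high GC content would not show in that rho and was not tested. The rho with transcript length, -0.20, lay between the bounds set for and against a length bias. The rho with genomic span was -0.16, the partial rho with transcript length given span -0.13 and that with span given length -0.041. A difference in RNA integrity or coverage along transcripts thus remains a candidate explanation. The value of -0.041 was under 0.05 in size, the bound set against an effect acting on long genomic spans. It did not clear that bound by the margin of 0.017 used for its error, so such an effect stays undecided. A biological preference for long messages, such as those of the Kmt2 genes, was not tested.

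Clock genes differed in a way that a different time of day at collection could give, but the labels name no time. The medians of Arntl, Npas2 and Clock and of Dbp, Per2, Per3, Nr1d1, Nr1d2 and Tef differed by 1.49 (0.03 against -1.46) in the authors' deposited table. All 6 of the latter were called lower, but of the former only Arntl was called, so the prediction was met in part. Collection time and an effect of the microbiota on the clock cannot be told apart here.

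Sex-linked genes did not settle which samples entered or whether the sign is as the header reads. The 4 Y-linked genes had a median of -1.03 in the authors' deposited table, with p-values of 0.417 to 0.621 that imply a standard error of about 1.38 (a measure of error chosen after the values were seen), and Xist was at -0.31 (adjusted p = 0.907). The median lay -0.13 from the log2 ratio of male shares of the differentiated cells, -0.62 from that of all samples and -0.47 from that without the second-batch sample, all within that error. The X-linked Kdm5c (-0.11) and Eif2s3x (0.08) had deposited p-values of 0.509 and 0.644 at far smaller changes, so their error was smaller. The large Y-linked error goes with samples of both sexes and no sex term, which would leave the uneven sex ratio unadjusted in the calls. A low level of the Y-linked genes could also widen it, and level is not given. That would not account for Xist, whose error was large as well. Its change of -0.31 was larger than that of Kdm5c, yet its deposited p-value was 0.850. With 1 of 2 SPF and 0 of 2 GF stem cell samples male, a median above 2 was predicted for stem cells alone. A median under 0 was to count against them. The observed -1.03 meets that bound against stem cells alone and lies below 2 by more than the error of 1.38. By a looser bound adopted after the values were seen, the error of 0, it is undecided. A sign opposite to the header would give a positive median with the other sets, but -1.03 is within the error of 0. With the header's sign, Xist would lie at 0.83 for differentiated cells, 0.32 for all samples, 0.49 without the second-batch sample and -1 for stem cells alone. Its observed sign is that of stem cells alone, opposite to the other sets, but its adjusted p of 0.907 leaves this undecided. Reg3g and Igha, known to be induced by gut bacteria, were higher in SPF with the header's sign in the authors' deposited table, the sign used throughout. Nnt, which would mark a difference in substrain, had 0 entries, so that question stays open too.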
